A study of Mus musculus with 5 samples.

How the data were processed

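Total RNA was extracted with Trizol from irradiated cultures of 3 mouse stromal lines, 6 µg per sample was made into biotin-labelled cRNA, and each of 5 samples was hybridised to an Affymetrix mouse array of 45101 probe sets. The groups were the lines EL08-1D2 (2 arrays), UG26-1B6 (2 arrays) and AM20-1B4 (1 array). The labels call the paired arrays biological replicates and do not say how the cultures were kept apart, so the spread is that between these samples. Nothing pairs replicate 1 of a line with replicate 1 of another, and no block was used.

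The deposited values are linear probe set signals (unit: intensity), made with MAS5 per the submitters' processing notes, with neither version nor scaling target stated. MAS5 commonly scales arrays to a shared mean, but the trimmed means (from 2% to 98% of each array's values) differed up to 1.56-fold between arrays. The design fixed before the data were examined took the values as deposited without further scaling, and that was kept. Quantile-normalised values, planned as an alternative, are printed beside the totals of genes called and of genes set apart. Counts of gene list members are from the deposited values except where stated, and those after normalization were often larger. The brightness difference between the EL08-1D2 arrays widens the spread of every gene, so the test on the deposited values has less power than the one after normalization: the median SE was 0.411, 0.503 and 0.503 for the 3 comparisons as deposited and 0.118, 0.144 and 0.144 after quantile normalization. The number of arrays limits the precision of every value.

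Signals were transformed as log2(signal + 11.3), the pseudocount being 10% of the mean trimmed mean. It pulls differences of dim genes towards 0. Probe sets were kept when they reached 22.5, the floor of 2 pseudocounts, on at least 1 array, which 21810 probe sets (48.4%) did. Gene symbols came from the platform's annotation: 34945 probe sets had 1 symbol, 932 had several, 9160 had none and 64 were controls, and only the first kind entered the gene tests. Each gene was read from its kept probe set with the highest mean, giving 11050 genes. Of the 1-gene probe sets 99.4% had an Entrez identifier in the RefSeq table of assembly GRCm38.p6, which was used only for chromosome and gene order.

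Differences were tested with limma 3.58.1 in R 4.3.3, with 1 coefficient per line on all 5 arrays, 3 contrasts and empirical Bayes moderation with a trend. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 difference of at least 1. The fit had 2 residual degrees of freedom, all from the EL08-1D2 and UG26-1B6 pairs. On the deposited values the prior degrees of freedom were infinite, so every gene of a given brightness shares a common spread and very small p-values rest on that assumption, while after quantile normalization they were 7.24. Genes set apart in a line were those called in the same direction against both other lines, compared with 100 simulations of unchanged lines.

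The 35 gene lists were written before the data were examined, and 34 with at least 4 measured members were tested with camera at a preset correlation of 0.01, two-sided, adjusted over 102 tests. Camera with an estimated correlation and fry were run beside it, and member counts were also adjusted over each list alone. Named genes followed a rule fixed at the same time. It took the 12 highest and 12 lowest called differences of UG26-1B6 against EL08-1D2 whose arrays do not overlap, and the 10 highest and 10 lowest genes set apart in AM20-1B4 with 6 and 6 for each other line. It also took up to 4 called members of each list in each comparison, and Kitl, Cxcl12, Sfrp1, Wnt5a, Ptn, Dlk1 and 5 sex-linked genes whatever their value. Genes outside the rule are said to be chosen after their values were seen.

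The steps were tested on simulated data with 50 changed genes per size among 11050. The simulated arrays carried the brightness differences of the data, which widen every SE on the deposited scale, so 0 false calls there measure little. A difference of 1 lies at the cutoff for a call, so part of these must miss it. As deposited, UG26-1B6 against EL08-1D2 recovered 0%, 36%, 92% and 100% of log2 differences of 1, 1.5, 2 and 3, AM20-1B4 against EL08-1D2 recovered 0%, 4%, 64% and 98%, and AM20-1B4 against UG26-1B6 recovered 0%, 0%, 72% and 98%, with 0 false calls in each. After quantile normalization the 3 comparisons recovered 56%, 52% and 52% of differences of 1, with 1, 2 and 0 false calls. Alternatives tried were quantile normalization, a shift to equal medians, other pseudocounts and filters, every probe set on its own, no probe sets of the _x_at and _s_at kinds, no variance trend, treat with a threshold of 0.5, fits of only the 2 lines compared, each replicate left out, a replicate block and other set tests. Quantile normalization joined with an estimated correlation, with fry and with each replicate left out was added after the data were seen. No column of the deposited table was left out, and the table holds no detection calls.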

Results

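Gene expression was measured in 3 mouse stromal cell lines made from midgestation embryos. EL08-1D2 came from embryonic liver at E11.5, UG26-1B6 from the urogenital ridge at E11.5, and AM20-1B4, per its label, from aorta and mesenchyme at E10.5 (embryonic days). Stromal cells of this kind are used as feeder layers for hematopoietic stem cells in coculture. All cultures were irradiated at confluence with 30 Gy and harvested 1 week later, so the values describe irradiated feeders. EL08-1D2 and UG26-1B6 had 2 arrays each, called biological replicates, and AM20-1B4 had 1 array without a replicate. In every comparison with AM20-1B4, that array was assumed to vary like the replicate pairs of the other lines. Levels are deposited signals, given as mean ± SD over 2 arrays for EL08-1D2 and UG26-1B6 and as the single value for AM20-1B4. Differences are log2 differences with their standard error (SE). In all, 11050 genes were tested.

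Replicates of a line correlated more closely with each other than with arrays of other lines. Across genes, Pearson's r was 0.989 between the EL08-1D2 arrays and 0.991 between the UG26-1B6 arrays. Between lines r ran from 0.890 to 0.939, and UG26-1B6 and AM20-1B4 were the closest lines at 0.938 and 0.939. Genes are not independent replicates, so these r values describe the arrays and test nothing. The arrays were not at a common brightness. The trimmed mean signal was 134 and 85.9 in EL08-1D2, 105 and 122 in UG26-1B6 and 116 in AM20-1B4, so that the brightest array stood at 1.56 times the dimmest. On the deposited values the median absolute log2 difference was 0.58 between the EL08-1D2 arrays, above the 0.29 to 0.56 between arrays of different lines, and 0.22 between the UG26-1B6 arrays. After quantile normalization it was 0.12 within each line and 0.27 to 0.39 between lines. The 3' over 5' signal ratio of the Gapdh control, a sign of RNA quality, lay between 0.865 and 0.919 on the 5 arrays, and that of Actb between 1.22 and 1.38. Totals of genes called and set apart after quantile normalization, which removes the brightness difference, are therefore given beside those from the deposited values. That normalization moved the median difference over all genes from 0.12 to -0.0033 for AM20-1B4 against EL08-1D2, from 0.07 to -0.02 for UG26-1B6 against EL08-1D2 and from 0.03 to -0.0099 for AM20-1B4 against UG26-1B6.

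The first comparison asked how the urogenital ridge line differed from the embryonic liver line. UG26-1B6 carried far more transcript of Dlk1, an imprinted gene for a transmembrane protein of the Notch ligand family, whose signal was 3823 ± 294 against 8.55 ± 10.1 in EL08-1D2 (log2 difference 7.69, SE 0.45, n = 2 per line). That probe set is of the _s_at kind, which can read several transcripts, and without such probe sets the Dlk1 difference was 3.76. Ndn, the imprinted gene for necdin, stood at 1536 ± 245 against 5.25 ± 0.0707 (6.54, SE 0.44). Ctsz, the gene for the lysosomal protease cathepsin Z, was at 4.45 ± 3.18 in UG26-1B6 and 3016 ± 968 in EL08-1D2 (-7.57, SE 0.45). Mmp2, which encodes gelatinase A, was at 17.6 ± 5.73 against 2399.6 ± 421 (-6.39, SE 0.45). Signals under the floor of 22.5 have no order among themselves, so these log2 differences depend on the pseudocount.

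Other genes with higher signal in UG26-1B6 were the amino acid transporter gene Slc6a15 (4.80), Pmaip1, which encodes the proapoptotic protein Noxa (4.79), the T-box transcription factor gene Tbx20 (4.77), Plac8 (4.52), 1700007K13Rik (4.29), Stox2 (4.10), the RNA-binding protein gene Elavl2 (4.10), the proliferation marker Mki67 (4.06), the VEGF receptor gene Kdr (4.02) and Tfpi, the tissue factor pathway inhibitor (3.96). Genes with lower signal in UG26-1B6 were Sprr2h (-6.03), the extracellular superoxide dismutase gene Sod3 (-5.74), the Y-linked Eif2s3y (-5.71), the carboxypeptidase gene Cpm (-5.64), the thrombomodulin gene Thbd (-5.55), the prostacyclin synthase gene Ptgis (-5.39), Cnp (-5.12), the neutrophil chemokine gene Cxcl5 (-4.92), Cd99 (-4.82) and Wfdc17 (-4.79). The SE of these log2 differences ran from 0.36 to 0.45. Sprr2h was read only from an _s_at probe set, so it could not be tested without such probe sets.

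In limma, 1394 of the 11050 genes passed an adjusted p of 0.05 and a log2 difference of at least 1, 793 higher and 601 lower in UG26-1B6. After quantile normalization 1607 genes passed, 820 higher and 787 lower, and 1341 genes passed in both. The 2 arrays of each line did not overlap for 5221 genes, 47.2% of those tested, and for all 1394 that passed. The 33.3% that chance gives for arrays of equal brightness is no fitting baseline here. EL08-1D2 replicate 1 was brighter and replicate 2 dimmer than both UG26-1B6 arrays, which lowers that share for unchanged genes. The number of genes that passed depended on which pair of arrays gave the spread. It rose without EL08-1D2 replicate 1 and fell without either UG26-1B6 replicate, where the lone array was assumed to vary like the pair of the other line. After quantile normalization it moved far less. Of the 169 differences in this comparison that are named here or belong to the genes picked by the same rule, 76 passed whichever replicate was left out, and the largest that did not was 3.31 in size.

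Cell cycle genes were higher as a group in UG26-1B6 than in EL08-1D2. Of the 47 measured genes for cell cycle and DNA replication, 40 were higher in UG26-1B6 and none lower, with a median log2 difference of 2.16 (42 higher when adjusted over the list alone). Mki67, the cyclin gene Ccnb2 (3.87), the mitotic kinesin gene Kif20a (3.66) and the survivin gene Birc5 (3.59) differed most. The median signal of the group was 237 and 266 on the UG26-1B6 arrays and 49.1 and 31.6 on the EL08-1D2 arrays, where 13 and 16 of the genes lay under the floor. Some genes of the p53 and DNA damage response were also higher, 11 of 35, with 1 lower and a median of 0.62 (13 and 1 adjusted over the list alone). Pmaip1, the membrane protein gene Perp (3.75), the cell cycle arrest gene Rprm (3.41) and the apoptosome gene Apaf1 (2.10) led this group. The lower gene was Mdm2, which encodes the ubiquitin ligase that restrains p53, at -1.56, and Cdkn1a, which encodes the cell cycle inhibitor p21, was higher at 1.60; these 2 genes were chosen after their values were seen. The camera test gave adjusted p = 3.01e-42 for the cell cycle list and 9.01e-06 for the p53 list with a preset correlation of 0.01, and adjusted p = 0.998 for both with an estimated correlation. With an estimated correlation all 102 camera tests gave adjusted p = 0.998, so that value tells no list from another. The correlation was estimated from 2 residual degrees of freedom. In these the brightness difference between the EL08-1D2 arrays (median log2 difference 0.58) moved genes together, so the value cannot decide for or against a list. After quantile normalization no list passed with an estimated correlation either. The preset correlation treats the genes of a list as nearly independent, and the very small p-values rest on that.

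Genes of the interferon response and of inflammation were lower in UG26-1B6. Of 40 interferon-stimulated genes 28 were lower and none higher, with a median of -1.73 and the same 28 and 0 adjusted over the list alone. The GTPase gene Iigp1 (-3.33), the MHC class I gene H2-K1 (-3.32), Oas1a (-3.10) and Oasl2 (-2.94) had the largest differences. H2-K1 was read only from probe sets of the _x_at kind, so it could not be tested without such probe sets. Of 23 chemokine and cytokine genes 12 were lower and 1 higher, with a median of -1.18 (14 and 1 adjusted over the list alone), among them Cxcl5, Ccl5 (-4.27), Il6 (-3.72) and Ccl9 (-3.33). In the complement list 3 of 8 were lower (4 adjusted over the list alone), namely Clu (-4.33), C1ra (-1.48) and Cd59a (-1.44), with a list median of -0.97. With the preset correlation the adjusted p was 1e-28 for interferon-stimulated genes, 6.11e-17 for chemokines and 0.0007 for complement, and adjusted p = 0.998 for each with an estimated correlation.

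Some genes of the extracellular matrix were lower in UG26-1B6 as well, while those of the basement membrane went both ways (3 of 18 higher and 2 lower, median -0.07, adjusted p = 0.993). Of 28 matrix proteases and inhibitors 10 were lower and 1 higher, with a median of -0.98 (12 and 1 adjusted over the list alone), led by Mmp2, Serpinf1 (-4.63), Mmp10 (-2.02) and the tissue plasminogen activator gene Plat (-1.94). Among 32 proteoglycans and matricellular proteins 9 were lower and 1 higher, with a median of -0.53 and the same counts adjusted over the list alone, and the largest differences were those of Mfap5 (-3.66), Sparcl1 (-3.34), Fbln1 (-2.89) and Gpc1 (-2.70). Of 16 collagen genes 5 were lower, also adjusted over the list alone, with a median of -0.63, among them Col3a1 (-3.33), Col6a3 (-1.89), Col23a1 (-1.69) and Col1a2 (-1.35). Of 20 genes for the contractile apparatus of smooth muscle and pericytes 6 were lower and 2 higher, also adjusted over the list alone, with a median of -0.46, and the largest were Myl9 (-1.72), Actg2 (-1.67), Mylk (-1.58) and Acta2 (-1.23). The adjusted p with the preset correlation was 7.49e-08 for proteases, 1.24e-05 for proteoglycans, 0.00112 for collagens and 0.0292 for smooth muscle, and adjusted p = 0.998 for each with an estimated correlation. The smooth muscle list missed the threshold without EL08-1D2 replicate 2 (adjusted p = 0.0919) and with no filter on dim probe sets (0.0968).

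Factors known to act on hematopoietic cells went both ways between the liver and urogenital ridge lines. Of 19 measured, 5 were lower and 1 higher in UG26-1B6, also adjusted over the list alone, with a median of -0.29. Il6, the BMP antagonist gene Grem1 (-3.29) and Angpt1, which encodes the Tie2 ligand angiopoietin 1 (-2.54), were lower, and Dlk1 was higher. Ptn, the gene for the heparin-binding cytokine pleiotrophin, was at 957.9 ± 224 in UG26-1B6 and 2878.7 ± 619.6 in EL08-1D2 (-1.58, SE 0.41). Kitl, the gene for stem cell factor, was at 576.8 ± 62.9 against 636.5 ± 255 (-0.09, SE 0.46, adjusted p = 0.970), and the chemokine gene Cxcl12 at 1618 ± 173 against 2586 ± 618 (-0.66, SE 0.41, adjusted p = 0.388). After quantile normalization Kitl was at -0.14 (adjusted p = 0.217) and Cxcl12 at -0.68 (adjusted p = 3.00e-05), the latter short of the log2 difference of 1 required for a call. The list had adjusted p = 0.0441 with the preset correlation and 0.998 with an estimated correlation, and it missed the threshold without EL08-1D2 replicate 2 (adjusted p = 0.137) and without UG26-1B6 replicate 1 (0.131). It also missed it with a pseudocount of 1 (0.0715), with no filter (0.10), with a filter on the mean (0.0775) and without a variance trend (0.0605).

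Of 32 Wnt pathway genes 7 were higher and 5 lower in UG26-1B6, also adjusted over the list alone, and the list did not pass (median -0.03, adjusted p = 0.929). The secreted Wnt inhibitor genes Sfrp2 (-3.63) and Sfrp1 (-2.72) were lower, and the Wnt agonist gene Rspo3 (2.59) and the Wnt receptor gene Ror2 (2.28) were higher. Sfrp1 stood at 475.1 ± 38.7 in UG26-1B6 and 3223 ± 659 in EL08-1D2, and Wnt5a at 230.2 ± 33.3 against 69.8 ± 26.5 (1.61, SE 0.41). Of 28 genes of urogenital ridge, gonad and kidney mesenchyme 4 were higher and 4 lower, also adjusted over the list alone, with the T-box genes Tbx3 (-2.40) and Tbx2 (1.48), the forkhead gene Foxd1 (2.27) and Eya1 (1.38) differing most, and this list did not pass (median 0.12, adjusted p = 0.789). The differences of Sfrp1, Ptn and Wnt5a lost their call without either UG26-1B6 replicate, where the spread came only from the EL08-1D2 pair with its unequal brightness.

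**Figure D1:**
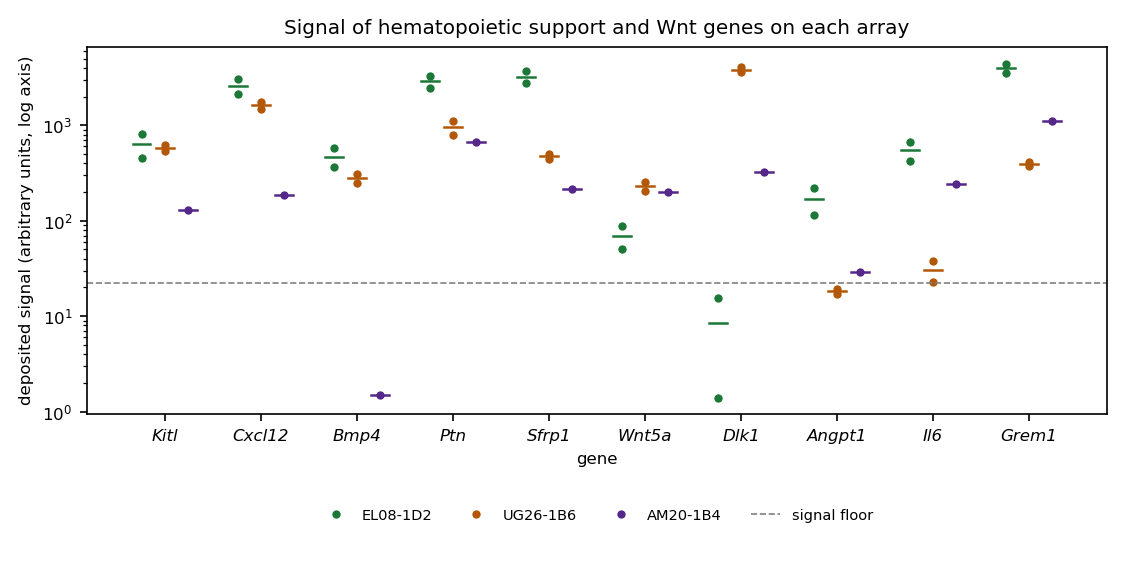
Deposited signal (log axis, arbitrary units) of 10 genes for factors that act on hematopoietic cells or on Wnt signalling in the 3 stromal lines. Points are arrays, bars the mean of a line, and the dashed line the signal floor of 22.5. Kitl and Cxcl12 are lowest in AM20-1B4, at 129 and 186.

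For 7 further lists the test passed on the deposited values and not after quantile normalization. Of 16 Notch pathway genes 3 were higher, Dlk1, Notch1 (2.06) and Dlk2 (1.60). Of 7 endothelial genes 3 were higher, Kdr, the TGF-beta coreceptor gene Eng (2.95) and the VEGF receptor gene Flt1 (1.23). Of 7 neural genes 3 were higher, Tubb3 (2.39), Nrcam (2.09) and Ncam1 (1.73). Among 13 genes of hepatic mesenchyme 4 were lower, Cygb (-2.46), Hand2 (-2.19), the PDGF receptor gene Pdgfra (-1.67) and Rgs5 (-1.17). In that list the median was 0.07, while its mean was -0.47 and its test pointed down. Of 6 chondrocyte genes the matrilin genes Matn4 (-1.60) and Matn2 (-1.29) were lower. Of 13 retinoid genes Tgm2 (-2.54) and Rarres2 (-1.59) were lower and the retinoic acid hydroxylase gene Cyp26b1 (1.62) higher. Of 34 genes for glutathione and xenobiotic metabolism 6 were lower and 1 higher (7 and 1 adjusted over the list alone), among them Nqo1 (-3.61), Gstt1 (-2.49) and Mgst2 (-2.33). For the other 6 lists the counts adjusted over the list alone were the same. The adjusted p before and after quantile normalization was 0.0107 and 0.209 for Notch, 0.000901 and 0.166 for endothelial, 0.0132 and 0.111 for neural, 0.0377 and 0.269 for hepatic mesenchyme, 0.0324 and 0.0563 for chondrocyte, 0.0490 and 0.0959 for retinoid and 0.0107 and 0.0836 for glutathione genes, and 0.998 for each with an estimated correlation.

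The second comparison set AM20-1B4 against the embryonic liver line. AM20-1B4 carried more transcript of Gpx3, which encodes the secreted glutathione peroxidase, with a signal of 4164 against 21.4 ± 3.54 in EL08-1D2 (7.0, SE 0.46). Ndn was at 1519.6 (6.53, SE 0.54), the cornified envelope gene Lce1f at 981 (5.53, SE 0.44), and Dlk1 at 328 (4.20, SE 0.55). Signals were lower for Ifi202b at 4.50 against 1716 ± 560.4 (-6.74, SE 0.56), Mcts1 at 1.10 against 891 ± 242 (-6.16, SE 0.55), Bmp4, the gene for a bone morphogenetic protein, at 1.5 against 469 ± 149 (-5.20, SE 0.52), and Cxcl12 at 186 (-3.70, SE 0.51). Ifi202b was read only from an _s_at probe set. Kitl was at 129 (-2.15, SE 0.56, adjusted p = 0.00295). Wnt5a was at 202 (1.44, SE 0.51, adjusted p = 0.0554) and passed after quantile normalization (1.32, adjusted p = 6.93e-05) and without EL08-1D2 replicate 1 (5.82e-07) or 2 (0.00521). Without _s_at probe sets the Dlk1 difference was 1.23 (adjusted p = 0.0608).

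In this comparison 867 genes passed, 519 higher and 348 lower in AM20-1B4, where 1 array stood against 2. After quantile normalization 1501 passed, 779 higher and 722 lower, and 855 passed in both. The count was 2174 and 1674 without EL08-1D2 replicate 1 or 2 and 302 and 291 without UG26-1B6 replicate 1 or 2, which entered through the spread. Of the 144 named differences 71 passed whichever replicate was left out, and the largest that did not was 3.17 in size. Kitl lost its call without either UG26-1B6 replicate and in a fit of the 2 lines alone, and so did Ptn (-2.08). In each of these fits the spread came only from the EL08-1D2 pair with its unequal brightness. Another Kitl probe set read 438.9 and 316.9 in EL08-1D2 and 79.8 in AM20-1B4, and the dimmer ones were also lowest in AM20-1B4.

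Many cell cycle and some p53 genes were higher in AM20-1B4 than in EL08-1D2, and some matrix and interferon genes lower, while basement membrane genes went both ways (2 of 18 higher and 2 lower, median 0.14, adjusted p = 0.779). Of 47 cell cycle genes 28 were higher and none lower, with a median of 1.53 (36 adjusted over the list alone), led by the ribonucleotide reductase gene Rrm2 (3.64), Ccnb2 (3.20), Cdc20 (3.17) and the centromere histone gene Cenpa (2.89). Of 35 p53 genes 11 were higher and none lower, with a median of 1.03 (17 and 1 adjusted over the list alone), led by Pmaip1 (3.67), Rprm (3.04), Perp (2.82) and the death receptor gene Fas (2.46). Of 32 proteoglycans and matricellular proteins 7 were lower, with a median of -0.50 (8 lower and 1 higher adjusted over the list alone), among them Ccn5 (-3.95), Sparcl1 (-3.63), the matrix Gla protein gene Mgp (-3.53) and Ogn (-2.83). Of 28 matrix proteases and inhibitors 6 were lower, with a median of -0.49 (7 adjusted over the list alone), among them Serpinf1 (-5.89), the cathepsin K gene Ctsk (-4.24), Adamts1 (-3.25) and Adamts5 (-2.01). Of 40 interferon-stimulated genes 6 were lower and 1 higher, with a median of -0.36 (7 and 1 adjusted over the list alone), and Psmb8 (-2.16), H2-K1 (-1.95), Oas1a (-1.67) and Zbp1 (-1.49) differed most. The adjusted p with the preset correlation was 5.77e-26, 8.40e-08, 3.44e-07, 2.10e-07 and 0.00111 for these lists in turn, and adjusted p = 0.998 for each with an estimated correlation; AM20-1B4 was assumed to vary like the other lines.

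Complement, collagen and growth factor lists were also lower in AM20-1B4 on the deposited and on the quantile-normalised values. Clu (-5.35) and C1ra (-1.66) were lower among 8 complement genes (3 adjusted over the list alone, median -0.65). Of 16 collagens 4 were lower, Col6a3 (-2.26), Col3a1 (-2.15), Col8a1 (-1.76) and Col6a2 (-1.63), and 1 was higher, Col7a1 (1.40), which was chosen after its value was seen (6 and 2 adjusted over the list alone, median -0.42). Of 35 fibroblast growth factors and receptor tyrosine kinase ligands 5 were lower and 2 higher, with Fgf18 (2.76), Kitl, Angpt1 (-2.08) and Pdgfra (-2.01) differing most (7 and 3 adjusted over the list alone, median -0.32). The adjusted p was 0.000341, 0.0307 and 0.0324 with the preset correlation and 0.998 for each with an estimated correlation, and with no filter on dim probe sets it was 0.0514, 0.190 and 0.440. Collagens also missed the threshold without UG26-1B6 replicate 1 (0.0931) or 2 (0.0998), with a filter on the mean (0.0559) and in a fit of the 2 lines alone (0.0855), and growth factors without UG26-1B6 replicate 1 (0.0629) and in a fit of the 2 lines alone (0.0609).

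A further 8 lists passed in this comparison on the deposited values and not after quantile normalization. Of 19 factors that act on hematopoietic cells 6 were lower and 3 higher, also adjusted over the list alone, with Bmp4, Dlk1, Cxcl12 and Kitl at the front. Of 32 Wnt genes 6 were lower and 1 higher (8 and 3 adjusted over the list alone), among them Sfrp1 (-3.83), the Wnt antagonist gene Dkk2 (-3.40), the ligand gene Wnt9a (2.93) and Rspo2 (-2.64). Of 23 chemokine genes 3 were lower and 2 higher (3 and 3 adjusted over the list alone), Il1rn (-3.08), Ccl8 (-3.02), Cxcl2 (1.70) and Cxcl16 (-1.49) among them. Of 13 hepatic mesenchyme genes 5 were lower, also adjusted over the list alone, with Cygb (-2.58), Pdgfra, Hand2 (-1.93) and the transcription factor gene Gata4 (-1.92) the largest. Of 13 retinoid genes Rarres1 (-1.54) was lower (2 adjusted over the list alone). Higher were 2 of 16 Notch genes (3 adjusted over the list alone), Dlk1 and Notch4 (1.58), 4 of 10 epithelial genes, also adjusted over the list alone, the desmoplakin gene Dsp (3.29), Perp, the keratin gene Krt19 (1.81) and Jup (1.78), and 2 of 7 neural genes, also adjusted over the list alone, Nrcam (3.16) and Ncam1 (1.89). The adjusted p before and after quantile normalization was 0.0101 and 0.0899 for hematopoietic factors, 0.0116 and 0.0542 for Wnt, 0.0217 and 0.0899 for chemokines, 0.0281 and 0.388 for hepatic mesenchyme, 0.0292 and 0.0559 for retinoid, 0.0281 and 0.0959 for Notch, 0.00234 and 0.453 for epithelial and 0.0133 and 0.127 for neural genes, and 0.998 for each with an estimated correlation. Genes for cholesterol and fatty acid synthesis, of which none of 26 passed singly in limma, none had an unadjusted p under 0.05 and 2 passed singly after quantile normalization, missed the list threshold on the deposited values (median -0.32, adjusted p = 0.112) and passed it after quantile normalization (-0.43, adjusted p = 0.00792).

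**Figure D2:**
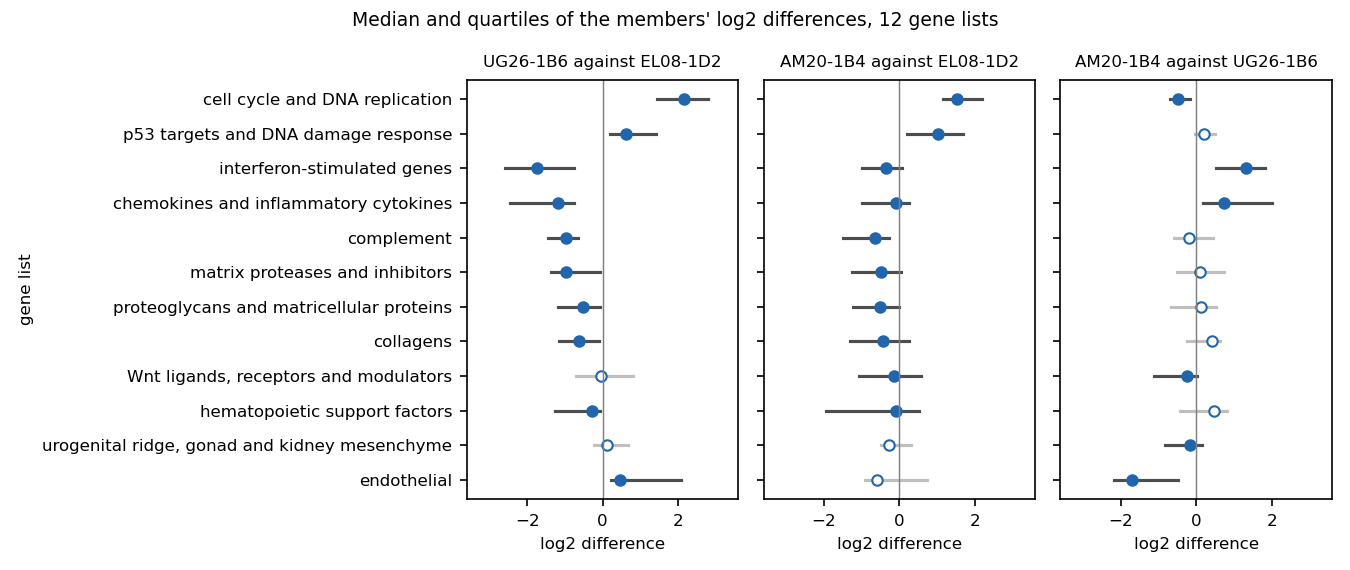
Median log2 difference (points) and quartiles (lines) of the measured members of 12 gene lists in the 3 comparisons of stromal lines. Filled points passed camera with a preset correlation of 0.01, and none passed with an estimated correlation. The cell cycle list lies at 2.16 and 1.53 in UG26-1B6 and AM20-1B4 against EL08-1D2, and interferon-stimulated genes lie at -1.73 and -0.36.

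The third comparison set AM20-1B4 against the urogenital ridge line, and fewer genes differed. Cathepsin Z, nearly without signal in UG26-1B6, was at 3102 in AM20-1B4 (7.64, SE 0.56). Gpx3 (7.59, SE 0.46), Lce1f (5.93, SE 0.44), the necroptosis effector gene Mlkl (5.46, SE 0.48), Ptgis (5.18, SE 0.56) and Cxcl5 (5.06, SE 0.55) were higher in AM20-1B4. Mcts1 (-5.81, SE 0.55), Ifi202b (-5.0, SE 0.56), Tbx20 (-4.94, SE 0.44), Elavl2 (-4.67, SE 0.44) and Bmp4 (-4.50, SE 0.52) were lower. Ndn, which differed between EL08-1D2 and both other lines, stood at -0.01 (SE 0.54) between AM20-1B4 and UG26-1B6. Kitl (-2.06, SE 0.56, adjusted p = 0.00942) and Cxcl12 (-3.04, SE 0.51) were lower in AM20-1B4, and Sfrp1 (-1.11, SE 0.53, adjusted p = 0.479), Ptn (-0.50, SE 0.50) and Wnt5a (-0.17, SE 0.51) did not pass. Sfrp1 passed after quantile normalization (-1.15, adjusted p = 2.67e-05), without EL08-1D2 replicate 1 (0.000837) or 2 (0.000870) and in a fit of the 2 lines alone (0.000846).

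Of the genes tested 382 passed, 225 higher and 157 lower in AM20-1B4, whose single array was assumed to vary like the replicate pairs. After quantile normalization 780 passed, 437 higher and 343 lower, and 376 passed in both. In the fits without a UG26-1B6 replicate, given next, the spread came only from the EL08-1D2 pair with its unequal brightness. The count was 816 and 819 without EL08-1D2 replicate 1 or 2 and 79 and 89 without UG26-1B6 replicate 1 or 2. Of the 99 named differences 36 passed whichever replicate was left out and the largest that did not was that of Dlk1 (-3.50, and -2.53 without _s_at probe sets), while Kitl and Cxcl12 were also lost without a UG26-1B6 replicate, Cxcl12 with adjusted p = 0.260 and 0.403 and Kitl with 1.00.

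Some interferon and inflammatory genes were higher in AM20-1B4 than in UG26-1B6. Of 40 interferon-stimulated genes 16 were higher and none lower, with a median of 1.33 (24 adjusted over the list alone), led by Ifit3 (2.78), Ifit1 (2.54), the deubiquitinase gene Usp18 (2.44) and Trim30a (2.31). The median signal of this group was 207 in AM20-1B4, 64.5 and 72.8 in UG26-1B6 and 308 and 204 in EL08-1D2. Of 23 chemokine and cytokine genes 9 were higher and none lower, with a median of 0.75 and the same 9 adjusted over the list alone, and Cxcl5, Ccl5 (3.79), Ccl9 (2.75) and Il6 (2.63) led them. The cell cycle list was lower in AM20-1B4 as a group, with a median of -0.48, although in limma none of its 47 genes passed singly or adjusted over the list alone, 5 had an unadjusted p under 0.05 and 4 passed after quantile normalization. Of 32 Wnt genes 4 were lower and none higher, Rspo3 (-1.83), Dkk2 (-1.63), Rspo2 (-1.55) and the receptor gene Ror1 (-1.46), with a median of -0.25 (8 lower and 1 higher adjusted over the list alone). The adjusted p with the preset correlation was 4.48e-23, 4.56e-14, 0.000133 and 0.00182 for these lists in turn, and adjusted p = 0.998 for each with an estimated correlation.

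Some endothelial and urogenital genes were lower in AM20-1B4 than in UG26-1B6. Of 7 endothelial genes 4 were lower, Eng (-3.53), Kdr (-2.21), Flt1 (-2.17) and Plvap (-1.69), with a median of -1.69 (4 lower and 1 higher adjusted over the list alone). Of 28 genes of urogenital ridge, gonad and kidney mesenchyme 3 were lower, Eya1 (-2.99), Gata4 (-2.17) and Maf (-1.95), and Tbx3 (1.76) was higher, with a median of -0.16 (5 and 1 adjusted over the list alone). In the smooth muscle list Tagln (2.06) and Des (1.47) were higher among 20 genes, in the chondrocyte list Matn4 (3.37) and Col11a1 (1.73) among 6, and in the muscle list Pax3 (1.49) and Des among 7 (2, 2 and 4 adjusted over the list alone). The adjusted p was 7.77e-08 for endothelial and 0.00919 for urogenital genes, and with no filter on dim probe sets 0.10 and 0.0659. For smooth muscle, chondrocyte and muscle it was 0.0490, 0.0216 and 0.0377 before and 0.0554, 0.549 and 0.0959 after quantile normalization, and all 5 lists had adjusted p = 0.998 with an estimated correlation.

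**Figure D3:**
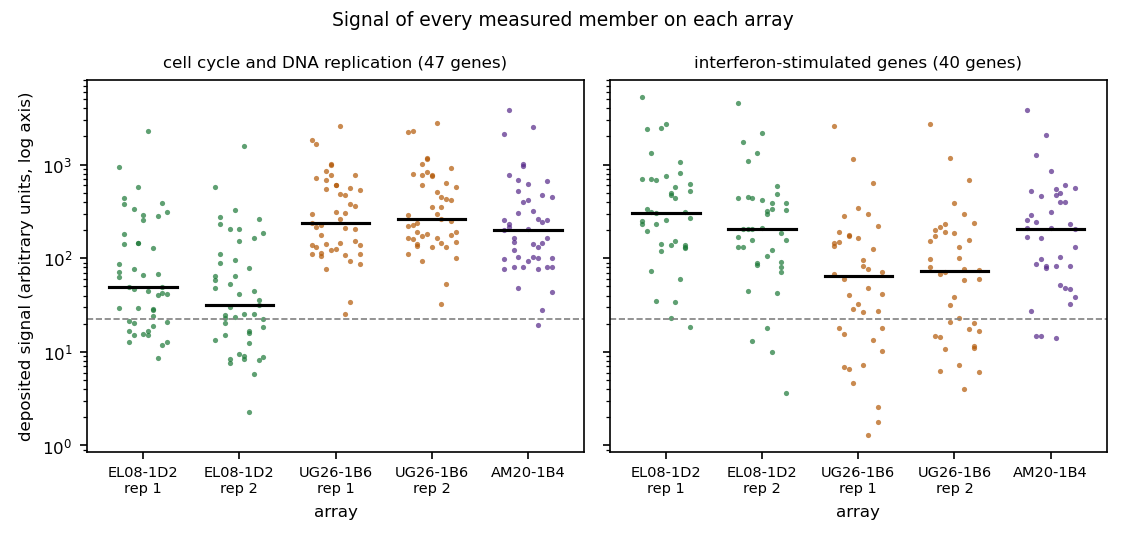
Deposited signal (log axis, arbitrary units) on each of the 5 arrays for 47 cell cycle genes and 40 interferon-stimulated genes. Points are genes, bars the median and the dashed line the signal floor of 22.5. The cell cycle medians are 49.1 and 31.6 in EL08-1D2 and 202 to 266 on the other arrays, and the interferon medians are lowest in UG26-1B6 at 64.5 and 72.8.

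Genes that differed from both other lines in the same direction set each line apart. They are ordered here by the smaller of their 2 log2 differences, which depends on the pseudocount where a line lies under the floor. Of the genes named below, Ifi202b and Lce1i were read only from probe sets of the _s_at and _x_at kinds. EL08-1D2 had 562 such genes, 224 higher and 338 lower. Cpm (3718 ± 631), Serpinf1 (3519.7 ± 1003.6), Clu (2091 ± 741), Eif2s3y (775.5 ± 301), Sod3 (744.1 ± 243) and the calcium channel subunit gene Cacng6 (277 ± 114) led the higher genes, and Ndn, 1700007K13Rik, Dlk1, Celf5, Pmaip1 and Stox2 the lower ones. UG26-1B6 had 182, of which 70 were higher, led by Tbx20, Elavl2, Plac8, Dlk1, Slc6a15 and the homeobox gene Hoxb13 (213 ± 13.6), and 112 lower, led by Ctsz, Ptgis, Mmp2, Thbd, Cxcl5 and Mlkl. AM20-1B4 had 151, of which 86 were higher, led by Gpx3, Lce1f, Xist, Lce1i, Sytl1, the myosin gene Myo5b, Bscl2, Car8, the glycogen phosphorylase gene Pygl and Ccr1l1, and 65 lower, led by Mcts1, Ifi202b, Bmp4, Ctsk, Mgp, Gpx7, Rpgrip1, Scara5, the homeobox gene Shox2 and Cxcl12. Independent lists of the same sizes would share 18.9 and 37.2 genes for EL08-1D2, 11.3 and 12.2 for UG26-1B6 and 10.6 and 4.94 for AM20-1B4, higher and lower in turn. In 100 simulations of unchanged lines sharing the same arrays no gene was called in any comparison, so their overlap of 0 was fixed beforehand and measures nothing, and part of the excess may come from the shared arrays. The differences of UG26-1B6 and AM20-1B4 against EL08-1D2 correlated across genes at r = 0.71 with a covariance of 0.463, where the shared EL08-1D2 arrays alone gave r = 0.41 and a covariance of 0.0122 in the simulations. After quantile normalization the counts were 873, 344 and 322.

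These counts moved with single arrays. Without EL08-1D2 replicate 1 or 2 they were 1286 and 988 for EL08-1D2, 329 and 360 for UG26-1B6 and 331 and 322 for AM20-1B4. Without UG26-1B6 replicate 1 or 2 they were 143 and 136, 39 and 36, and 34 and 41.

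The sex-linked genes differed between the lines. Xist, the RNA that coats the inactive X chromosome, was at 596 in AM20-1B4 and under the floor in EL08-1D2 (5.10 ± 3.68) and UG26-1B6 (6.30 ± 1.84). The Y-linked genes Eif2s3y, Kdm5d (85.5 ± 50.1) and Uty (73.5 ± 9.40) had signal in EL08-1D2 and lay under the floor on all arrays of UG26-1B6 and AM20-1B4. In UG26-1B6, therefore, neither Xist nor these Y-linked genes reached the floor, and Ddx3y was not among the measured genes.

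Markers of other cell types were mostly near or under the floor. Of 34 hematopoietic genes on the array 10 were measured, and Ptprc, Tyrobp, Fcer1g, Cd52 and Coro1a, expressed across blood cells, lay under the floor on all 5 arrays, as did the liver genes Alb and Afp and the endothelial genes Pecam1 and Cdh5; these genes were chosen after their values were seen. Of the hematopoietic list Csf1r was higher in UG26-1B6 (1.42) and in AM20-1B4 (2.31) than in EL08-1D2, and Cd68 was higher in AM20-1B4 (1.32), both also adjusted over the list alone. Of 2 further Csf1r probe sets, one read 27.2 and 20.2 in EL08-1D2, 54 and 52.2 in UG26-1B6 and 111.5 in AM20-1B4, and the other 55.8 and 41.7, 47.7 and 43.4, and 68.3. In the list for hepatoblasts and hepatocytes 2 of 26 genes were measured, Dlk1 and Foxa2 (1.03 in UG26-1B6 against EL08-1D2), too few for a list test. Of 10 epithelial and mesothelial genes 5 were higher and 2 lower in UG26-1B6 than in EL08-1D2, also adjusted over the list alone, among them Perp (3.75) and the mesothelin gene Msln (-2.88), and the list did not pass (adjusted p = 0.125).

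Several further lists passed in none of the 3 comparisons, although single members differed. Of 32 genes of BMP and TGF-beta signalling 6 were higher and 1 lower in UG26-1B6 than in EL08-1D2, also adjusted over the list alone, with Grem1, Eng, Gdf10 (2.10) and Inhbb (2.00) differing most. Of 18 genes of the insulin-like growth factor axis 3 were higher and 2 lower (3 and 3 adjusted over the list alone, 3 and 5 after quantile normalization). The binding protein gene Igfbp4 was at -3.27, and at -4.12 in AM20-1B4 against EL08-1D2. Of 25 integrins and adhesion molecules 4 were higher and 1 lower, also adjusted over the list alone, among them Pcdh17 (2.80), Ncam1 (1.73) and the integrin gene Itgb3 (-1.61). Of 19 adipocyte genes 3 were higher and 2 lower (3 and 3 adjusted over the list alone), with the lipoprotein lipase gene Lpl at -3.37 and the transcription factor gene Ebf2 at 4.52 in AM20-1B4 against EL08-1D2. Of 10 osteoblast genes Msx2 (1.60) and the alkaline phosphatase gene Alpl (1.18) were higher and Col1a1 (-1.07) lower, also adjusted over the list alone. Of 30 genes of hypoxia and glycolysis 2 were higher and 2 lower (2 and 3 adjusted over the list alone), with the lactate transporter gene Slc16a3 at 3.02. The lowest adjusted p that these 6 lists and the hematopoietic list reached in any comparison was 0.124, with 0.998 for each with an estimated correlation. Among lists that did not pass, the median, the mean and the test differed in sign for Wnt, insulin-like growth factor, basement membrane, adhesion, hematopoietic, osteoblast, axon guidance and imprinted genes in UG26-1B6 against EL08-1D2. They also differed for BMP, basement membrane, muscle, adipocyte and imprinted genes in AM20-1B4 against EL08-1D2. In AM20-1B4 against UG26-1B6 they differed for proteoglycans, complement, hepatic mesenchyme, neural and growth factor genes and for factors that act on hematopoietic cells (median 0.46, mean -0.15, adjusted p = 0.587).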

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

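The test of second probe sets was chosen before its result was seen, and the 4 tests on cell cycle genes after. An 18S ribosomal RNA control probe set, which no comparison used, read 1173.7 on the array of UG26-1B6 replicate 1, 17.8 times the highest other array (65.8 in UG26-1B6 replicate 2), and the matching 5' probe set read 1301.4 on it against 18.5 to 65.5 on the others. Its Gapdh ratio of 0.878 lay within the range of the other arrays, and the correlation with its replicate across genes was 0.991.

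Many genes had strong signal in 1 line and a signal under the floor in another, such as Ctsz, Dlk1 and Gpx3. A faulty or cross-hybridising probe set, or a sequence variant under it, could give such a pattern for a single probe set. Of the 812 further probe sets of genes called in UG26-1B6 against EL08-1D2, 90.9% had the same sign and at least 0.5 log2. For most of these, then, the difference was not confined to a single probe set. Probe sets under the floor on every array, as some of Ndn were, had been filtered out. Those that disagree by staying dark were thus not counted, and the share cannot decide on this cause for the called genes as a set. A probe set fault stays open, and nothing bears on it for genes with no further probe set, among them Gpx3, Mcts1, Bmp4 and Ifi202b. A difference between the lines' tissues of origin is an open explanation that was not tested, since each tissue is represented by a single line. Embryonic day (E10.5 for AM20-1B4 and E11.5 for the others) and the signals of sex-linked genes also differed between lines and cannot be told apart from tissue.

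Of 47 cell cycle genes 40 were higher in UG26-1B6 and 28 in AM20-1B4 than in EL08-1D2, 1 week after 30 Gy. The list passed with the preset correlation and not with an estimated correlation (adjusted p = 0.998 in both comparisons). The latter value was the same for all 102 camera tests on the deposited values, so it cannot decide for or against this list. Array brightness is unlikely to be the cause, as the median difference in UG26-1B6 was 2.02 after quantile normalization. Values at the floor in EL08-1D2 do not account for it either: the 16 genes with a mean EL08-1D2 signal of at least 4 floors had a median of 1.43. A lower level of the inhibitor gene Cdkn1a in the lines with more cell cycle transcript is argued against by a higher Cdkn1a in UG26-1B6 (1.60, SE 0.384) and in AM20-1B4 (2.24, SE 0.47). A weaker induction of Cdkn1a cannot be told apart from a different level before irradiation, since every array is of an irradiated culture. Whether the lines differ in dividing cells before or after irradiation stays open, since arrays of cultures without irradiation were not analysed here.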

How the results depend on the processing

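Quantile normalization with each replicate left out, with an estimated correlation and with fry were chosen after the data were seen. Within 1.5 times of the reported values stayed all 9 counts of genes called, genes set apart and lists under a pseudocount of 1 or 3 times larger, a filter on the mean, no _x_at and _s_at probe sets and no trend. Quantile normalization gave 1501 genes for AM20-1B4 against EL08-1D2, 780 against UG26-1B6, 873, 344 and 322 set apart in EL08-1D2, UG26-1B6 and AM20-1B4, and 10 and 9 lists against EL08-1D2. Shifting arrays to the same median gave 1419 and 665 genes for AM20-1B4 and 307 and 281 set apart in UG26-1B6 and AM20-1B4. No filter left 7 and 5 lists for AM20-1B4 against EL08-1D2 and UG26-1B6. Every probe set on its own, which tests more features, gave 2542, 1735 and 580, with 1052 and 227 set apart in EL08-1D2 and AM20-1B4. The stricter treat test gave 682, 415 and 174, with 249, 85 and 61 set apart. Fits of 2 lines, whose spread comes from 1 pair, gave 335 and 828 for AM20-1B4, with 235 and 337 set apart in EL08-1D2 and UG26-1B6. Replicates left out gave 357 to 2122, 291 to 2174 and 79 to 819 genes, and 136 to 1286, 36 to 360 and 34 to 331 set apart, while numbers of lists stayed within 1.5 times. After quantile normalization these were 1595 to 1650, 1474 to 1575 and 694 to 809, and 844 to 912, 327 to 348 and 278 to 319, so the wider ranges come with the unequal brightness of the EL08-1D2 arrays. Replicate deviations of the lines correlated at -0.05 across genes, so the numbers do not pair the arrays, and a replicate block, fitted for UG26-1B6 against EL08-1D2 alone, gave 622 genes where 1394 were reported, and 59 of 172 named gene values lost a call. With an estimated correlation in limma's camera 0, 0 and 0 lists passed (0, 0 and 0 at an unadjusted p under 0.05), with fry 0, 0 and 0 (5, 2 and 1 unadjusted), with quantile normalization and an estimated correlation 0, 0 and 0 (5, 3 and 2 unadjusted, lowest adjusted p 0.372), and with quantile normalization and fry 30, 31 and 21. Fry asks if a list's genes move on balance, not more than others. Of the 42 lists past the threshold with the preset correlation, 17 passed under every alternative that kept it. With quantile normalization and fry the median of osteoblast genes was -0.30 in UG26-1B6 and 0.10 in AM20-1B4 against EL08-1D2 and that of matrix proteases 0.0798 between AM20-1B4 and UG26-1B6, and the fry test of each pointed down where the reported camera test, which none passed, pointed up; the cause was not tested, nor that of other changes where none is given. Of up to 422 named gene values under each of 16 alternatives (172 under the block, and fewer than 422 where a gene was not tested), 5612 kept direction and side of the threshold, 846 lost and 10 gained a call, and 0 reversed. Of list results 1162 stayed, 212 lost, 47 gained and 3 reversed. Lists were not run with every probe set or treat. Genes near the floor of 22.5 have little signal over background, and their differences depend on the pseudocount.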

Other observations

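The tests on chromosomes were chosen after the result was seen, except the test of the medians on either side of the middle genes of chromosomes 4 and 18 together. Hox genes, which mark position along the body axis, differed gene by gene between the stromal lines, with 5 of 22 higher and 2 lower in UG26-1B6 than in EL08-1D2, also adjusted over the list alone. Hoxb13 (3.42, SE 0.36), Hoxb9 (2.96) and Hoxa9 (1.92) were higher in UG26-1B6 and Hoxd8 (-2.73) was lower. In AM20-1B4, whose array was assumed to vary like the others, Hoxa11 was higher (3.23) and Hoxd8 (-2.87) and Hoxd9 (-2.29) lower than in EL08-1D2, and Hoxc8 (1.72) and Hoxc9 (1.70) were higher than in UG26-1B6. Of 18 imprinted genes 4 were higher and 4 lower in UG26-1B6 (4 and 5 adjusted over the list alone). Beside Dlk1 and Ndn, Zdbf2 was higher (1.54) and Gatm lower (-3.15), and in AM20-1B4 the neuronatin gene Nnat was higher than in EL08-1D2 (2.60). Meg3, an imprinted RNA near Dlk1, was higher in AM20-1B4 than in UG26-1B6 (2.41), while Dlk1 was lower (-3.50, and -2.53 without _s_at probe sets). Neither list passed in any comparison, with adjusted p from 0.349 to 0.746 for Hox and from 0.124 to 0.776 for imprinted genes.

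Axon guidance genes went both ways, with 2 of 37 higher and 7 lower in UG26-1B6 than in EL08-1D2, also adjusted over the list alone. Slit3 (-1.87) and Slit2 (-1.67), which encode secreted guidance ligands, were lower in UG26-1B6 and lower in AM20-1B4 (-2.46 and -2.05), and the netrin gene Ntn1 was lower in AM20-1B4 than in EL08-1D2 (-3.32) and UG26-1B6 (-2.13). Of 18 basement membrane genes 3 were higher and 2 lower in UG26-1B6, also adjusted over the list alone, with Smoc2 (2.59) and the perlecan gene Hspg2 (1.98) higher and the nidogen gene Nid2 (-2.27) lower. Col18a1 was higher in AM20-1B4 than in EL08-1D2 (3.67) and UG26-1B6 (2.96). Neither list passed in any comparison, with adjusted p from 0.284 to 0.805 for axon guidance and from 0.732 to 0.993 for basement membrane.

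Medians over the genes of some chromosomes lay away from 0 between UG26-1B6 and EL08-1D2 after quantile normalization. The median difference was 0.49 over 279 genes of chromosome 18, 0.47 over 676 genes of chromosome 4, 0.30 for chromosome 12 and 0.28 for chromosome 10, and in AM20-1B4 against EL08-1D2 it was 0.51 for chromosome 12, 0.36 for chromosome 4 and 0.34 for chromosome 18. AM20-1B4 against UG26-1B6 gave -0.07 for chromosome 4 and -0.14 for chromosome 18, so the shift of these 2 was shared by both lines against EL08-1D2. The genes before and after the middle gene of UG26-1B6 against EL08-1D2 had medians of 0.0442 and 0.568 on chromosome 12, 0.145 and 0.438 on chromosome 10 and 0.122 and 0.688 on chromosome 4, so that most of the shift lay in part of each. Of the genes of chromosomes 4 and 18, 73.0% lay above the median of all genes (70.7% on 4 and 78.5% on 18), which restates the shifted medians of chromosomes picked for them. A few strongly changed genes cannot move a median over so many genes, so these values argue against that explanation for these 2 chromosomes. Between replicates of a line the largest chromosome median was 0.0318 in size, which argues against hybridisation differences between single arrays. A difference that went with the line would not show between its replicates and stays open. Random placement of genes gave at most 0.159 (permutation p = 1e-04, the smallest that 10000 draws can give), and the medians of 11 of 20 chromosomes lay beyond that, 7 above 0 and 4 under it, down to -0.21 for chromosome 8. This placement, like the random splits below, treats genes as independent. Neighbouring genes that vary together and the spread between cultures do not enter it, so the p-value and the count may overstate the evidence. Normalization holds the median over all genes near 0, so the 4 under 0 may follow from the others and are not counted as separate shifts. Shifts above 0 on 7 chromosomes still do not single out a different copy number of chromosome 18, in EL08-1D2 or in the other 2 lines. It stays open, as both sets of genes on either side of its middle gene had a median above 0.2, the smaller at 0.387, and the 2 medians differed by 0.14 where random splits of its genes gave up to 0.291 (permutation p = 0.0985). Chromosome 18 was picked for its large median in the same values, so medians above 0.2 on both sides add little. The test of chromosomes 4 and 18 together, fixed before its own result was seen but for chromosomes picked for their medians, was undecided. Its smallest median, 0.122, fell between the limits set for and against that cause. In a test chosen afterwards the 2 medians of chromosome 4 differed by 0.57, where random splits gave at most 0.256. This argues against a copy number change of all of chromosome 4 as the only cause of its shift. A change of part of chromosome 4 stays open, DNA was not measured, and regional regulation of transcription stays open.

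Other values stood apart without a test. The B1 repeat control read 613 on the AM20-1B4 array and 1565 to 3093 on the others. Neither Xist nor the Y-linked genes Eif2s3y, Kdm5d and Uty reached the floor in UG26-1B6.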
